A study of Mus musculus with 2 samples.

How the data were processed

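ATAC-seq libraries of embryonic mouse liver (day 16.5, strain B6NCrl) from 2 biological replicates were used as the authors' peak lists. Per the labels, tissue was tagmented with the Nextera enzyme, and the peaks are on mm10. The aligner, the peak caller, any shift of reads for the transposase and all versions are not given in the sources used here. The lists numbered 12: thresholded, pseudoreplicated and ranked peaks for each replicate, and 6 joint lists made from both. Their names refer to the irreproducible discovery rate (IDR), a measure of how well peak ranks repeat between 2 inputs. Thresholded lists hold the peaks that passed that measure, and ranked lists hold all peaks that entered it.

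The deposited lists give each peak a score that the authors scaled to a whole number, which was not analysed further. The signal value of each peak was deposited by the authors relative to a background the files do not define, and it was used only to describe, rank or filter peaks within a list. The −log10 p and −log10 q of each peak were deposited as the peak caller gave them, and the ranked lists add −log10 of the IDR and the −log10 p of the peak in both inputs. Of the joint ranked lists, 1 was taken as made from the replicates because 96.9% of the values of its first input occur in replicate 1's own ranked list and 96.6% of those of its second input in replicate 2's. The joint thresholded list holds 31650 merged peaks, and all of its summits occur in the second joint ranked list, whose inputs are not named in the sources used here. A peak of the joint list therefore need not have been called in each replicate.

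No file held read counts. Depth, and with it the limit of detection of each library, is unknown, and a gene without a peak is described as such and not as closed beyond detection. Exact binomial (Clopper-Pearson) intervals of shares cover counting over genes or peaks only. The replicates were grouped as the labels number them. The replicates are separate pools of embryos, and with 1 group no test between conditions was made. The p-values reported are across genes or peaks.

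The reference was GRCm38.p6, the assembly of mm10, with GENCODE release M21 (basic set). The last peak and the last annotated base lie inside every main chromosome. Protein-coding genes on chromosomes 1 to 19, X and Y numbered 21938. Intervals that overlap, which the lists give once per summit, were merged, and the summit with the highest signal was kept. Intervals on unplaced scaffolds were left out. Overlaps were counted in Python 3.11.15 with numpy 2.4.6 and scipy 1.17.1 and gave the same numbers with bedtools 2.31.1.

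Before the data were examined, 25 gene lists (markers of liver, blood and other cell types, pathways, a family and controls), 25 motif patterns, the tests and the alternatives were fixed. Of the listed genes, Ahsp had no match. A promoter was called open where a merged peak overlapped the 1 kb to each side of any start. Any annotated start counted, also one inside the gene, as for the peaks of Krt10 and Prtn3. The summit of such a peak could lie over 1 kb from the start, as for Spta1 and Olfr67. A peak could therefore count both for an open promoter and as distal. The share of each list was compared with all other protein-coding genes by two-sided Fisher's exact test. For distal peaks, whose summit lies over 1 kb from every start, the median number within 50 kb of the gene body was compared with 10000 random lists matched on deciles of gene length, in a two-sided permutation test. Motif matches on either strand within 100 bp of distal summits were compared with windows of 201 bp placed 1500 bp to each side that overlap no joint ranked peak, by two-sided Fisher's exact test, with log-scale 95% intervals of the ratio. The p-values were adjusted by the Benjamini-Hochberg method within each family, with a threshold of 0.05 and, for motifs, a ratio of at least 1.5 or its inverse. A promoter without CpG enrichment had an observed over expected CpG ratio under 0.6 within 500 bp of every start.

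The genes named are, per list, up to 4 with the highest promoter peak, up to 2 with the most distal peaks and up to 2 first in list order without a promoter peak, and over all protein-coding genes the 10 with the most distal peaks and the 10 highest distal peaks. Other genes, and the positions at the globin and albumin loci, were chosen after their values were seen.

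The tests were first run on simulated data. For the promoter comparison over 21938 genes, 97.3% of lists of 15 to 50 genes set to 95% open against 50% were recovered, with 0.805% of unchanged lists called. For the distal comparison over 21938 genes, 96.8% of such lists with 3 times the peaks were recovered and 0% of unchanged lists called. For the motif comparison over 4000 windows, all 5 implanted patterns and no other were called. The simulated windows had 1 base composition, whereas median GC in the data was 51.2% at distal summits and 45.8% in flanks. Simulated distal counts were independent between genes. All unchanged genes in the promoter simulation had the same chance of 50% to be open. In the data, 84.0% of genes with a CpG-rich promoter and 21.2% of the others were open. False calls from GC content, from the CpG class of promoters or from peaks shared between genes were thus not simulated. Lists set below other genes were not simulated either. Alternatives were the replicates' own lists, the other joint lists, the 50% of peaks with the highest signal, other windows and distances, unmerged intervals, other overlap rules, genes without a CpG-rich promoter, other matching of random lists, and other motif backgrounds. Copies of intervals elsewhere in the genome were sought with blastn 2.17.0.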

Results

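Accessible chromatin was measured by ATAC-seq, in which the Tn5 transposase inserts sequencing adapters into open DNA, in liver of B6NCrl mouse embryos at embryonic day 16.5. The fetal liver at this age is both a developing organ of hepatocytes and the main site of blood formation. The data formed 1 group of 2 biological replicates, each a pool of male and female embryos. The pool of replicate 2 held livers of 41 embryos. No second condition was present, so the comparisons below ask which genes and sequence elements were open in this tissue and how far the replicates matched. The authors' peak lists gave no read counts, so the depth of each library is unknown. After overlapping intervals were merged, the thresholded list of replicate 1 held 25288 peaks that covered 15.4 Mb, that of replicate 2 held 22772 peaks over 14.6 Mb, and the joint list made from both held 31650 peaks over 19.6 Mb, or 0.718% of the main chromosomes. Median peak widths were 551 bp, 590 bp and 547 bp in that order. Positions are in GRCm38 (mm10). Peak heights are the authors' signal values and were compared only within a list.

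Promoters of red blood cell genes and of fetal hepatocyte genes carried a peak in nearly every case, whereas 6 of the other 10 lists of cell type markers carried peaks less often than other genes. An open promoter here is one with a peak at the authors' threshold, and a gene without one may have a weaker peak. In the joint list, 31 of the 34 erythroid genes had a peak within 1 kb of a transcription start (91.2%, exact 95% interval 76.3 to 98.1%). The same was true of 29 of the 32 fetal hepatocyte genes (90.6%, 75.0 to 98.0%). Of all 21938 protein-coding genes, 11625 did (53%). Promoters of 18 of 18 housekeeping genes, such as Rplp0 (signal 21.6), and of 22 of 22 cell cycle genes, such as Ccnb2 (27.6) and Mcm3 (26.4), were also open in both replicates (adjusted p of 3.76e-05 and 7.57e-06, Fisher's exact test), as were those of 9 of 9 genes of heme synthesis. No promoter of the 15 muscle genes was open, and the olfactory receptors, a control family of sensory neurons, had 4 open promoters among 1093 genes (adjusted p of 0 at the precision of the software, Fisher's exact test). Of the 25 lists, 5 had a higher share of open promoters than all other genes, 11 a lower share and 9 did not pass the threshold by two-sided Fisher's exact test across genes with Benjamini-Hochberg adjustment over the lists. Genes are not replicates of the tissue, so these p-values describe the lists and not variation between livers.

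**Figure D1:**
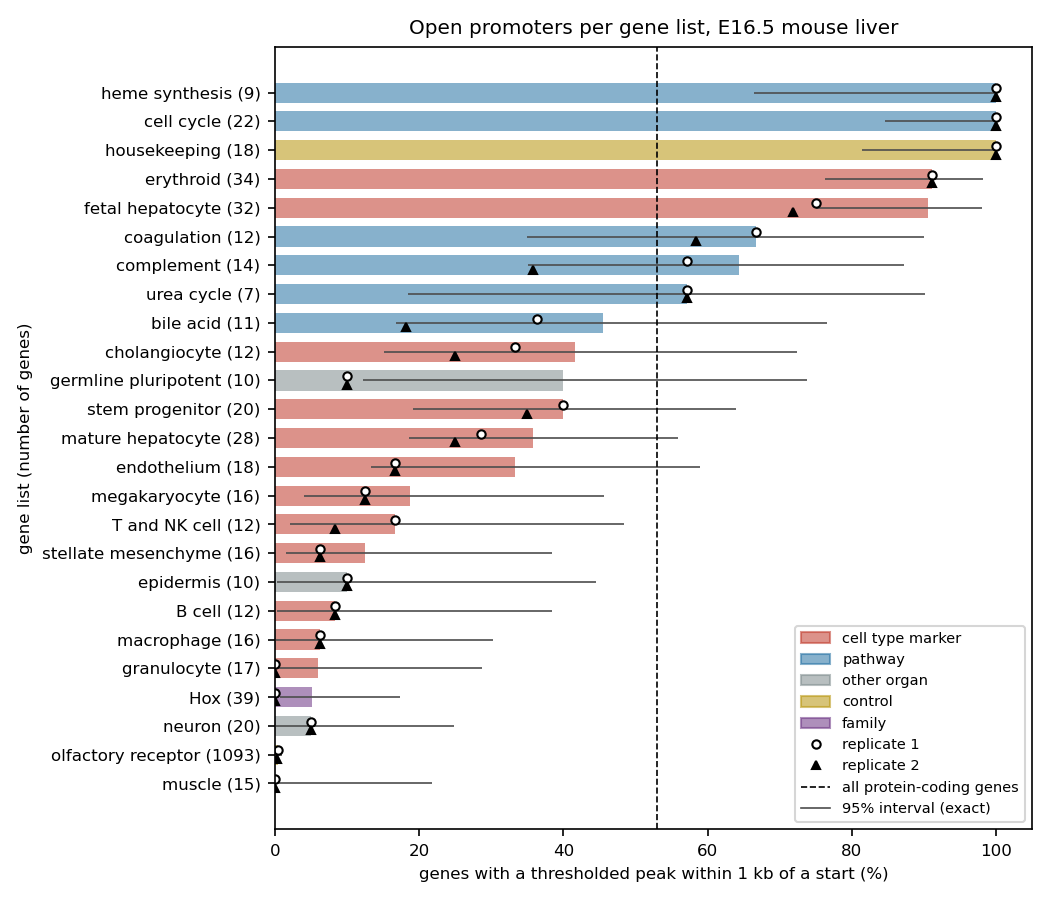
Share of genes (%) in each fixed list with a joint thresholded peak within 1 kb of a start (bars, coloured by kind of list), with exact 95% intervals and the shares in the own lists of replicate 1 (circles) and replicate 2 (triangles). Erythroid genes stood at 91.2% and muscle genes at 0%, and the dashed line marks 53% for all protein-coding genes.

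Among erythroid genes (adjusted p = 1.57e-05, Fisher's exact test), the 4 highest promoter peaks belonged to Trim10, Spta1, Epb42 and Gypa. Trim10 had a peak on chromosome 17 from 36869275 to 36869667 with signal 25.0 and a summit 129 bp upstream of a start. Spta1, which encodes alpha-spectrin of the red cell membrane, had a peak of signal 24.5 on chromosome 1 from 174171573 to 174171955. The peak of Epb42, which encodes protein 4.2 of the same membrane skeleton, reached 23.7, and that of Gypa, which encodes glycophorin A, reached 19.6. The same 31 erythroid promoters were open in the joint list and in both replicates' own lists. Both adult beta-globin genes were open: Hbb-bt carried a peak on chromosome 7 from 103813323 to 103814181 with signal 13, and Hbb-bs carried one from 103827341 to 103828221 with signal 12.8. The embryonic beta-like genes Hbb-y and Hbb-bh1 had no promoter peak in any of these 3 lists or in the more permissive pseudoreplicated list. The third erythroid gene without one was Gfi1b, a transcriptional repressor of the lineage, which had a promoter peak in the pseudoreplicated list. The alpha-globin genes Hba-a1 and Hba-a2 were open too, but these copies are near-identical, as are Hbb-bt and Hbb-bs, so how reads were shared between them is uncertain. All 9 heme synthesis genes were open in both replicates (adjusted p = 0.00848, Fisher's exact test). They included Cpox (signal 19.9), Ppox (17.4), Urod (15.9) and Uros (14.9). Alas2, the red cell form of the first enzyme of the pathway, had a lower peak of signal 6.67.

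Among fetal hepatocyte genes (adjusted p = 3.76e-05, Fisher's exact test), the 4 highest promoter peaks belonged to Foxa3 (signal 17.1), Hnf4a (16.7), Fga (15.3) and Apob (15.1). Foxa3 and Hnf4a encode transcription factors of hepatocytes, Fga encodes a fibrinogen chain and Apob the main protein of low-density lipoprotein. The Hnf4a peak lay on chromosome 2 from 163546972 to 163547628, with its summit 66 bp upstream of a start. Alb, the albumin gene, had a lower promoter peak of 7.68 that was called in replicate 2 and not in replicate 1. Afp, which encodes alpha-fetoprotein, had no promoter peak at the threshold in either replicate or the joint list and 6 distal peaks within 50 kb. Apom and Nr1h4 also had none, and all 3 had one in the pseudoreplicated list. The replicates' own lists gave 73.4% ± 2.21 open promoters (SD, n = 2), with 24 genes in replicate 1, 23 in replicate 2 and 20 in both. Peaks of Fgb, Vtn, Foxa1 and Prox1 were called in replicate 1 and not in replicate 2, and those of Foxa2 and Onecut1 in replicate 2 and not in replicate 1. With the 50% of joint peaks of highest signal, the fetal hepatocyte list was not past the threshold (a difference from other genes of -11.3 percentage points), while the erythroid list stayed above.

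Of genes of the mature hepatocyte, 10 of 28 were open (35.7%, adjusted p = 0.128, Fisher's exact test), a share that did not differ from other genes at the threshold. Glul (signal 17.6), Abcc2 (15.7), Pck1 (13.8) and Hpd (12.1) led this list. Cyp2e1 and Cyp7a1, which encode a drug-metabolising enzyme and the rate-limiting enzyme of bile acid synthesis, had no promoter peak at the threshold. Cyp7a1 had one in the pseudoreplicated list and Cyp2e1 did not. With either replicate's own list, the mature hepatocyte list was below other genes past the threshold, with differences of -23.6 percentage points in replicate 2 and -21.5 in replicate 1, as it was with the higher-signal 50% of joint peaks (-28.3) and with a window of 500 bp (-27.2). The difference was 2.98 with the replicated joint list and 12.2 among genes without a CpG-rich promoter, past the threshold in neither. Mup20, Cyp2c29 and Cyp3a11 belong to families of near-identical copies, and their state is uncertain. Of the liver pathways, 8 of 12 coagulation genes were open (66.7%), led by Pros1 (16.0) and F10 (15.7), and 9 of 14 complement genes (64.3%), led by Mbl1 (14.5), Cfh (13.7) and C8b (12.5). In the replicates' own lists, 8 complement promoters were open in replicate 1 and 5 in replicate 2. Of the urea cycle, 4 of 7 genes were open, with Asl (16.2) and Ass1 (13) at the top. Cps1 and Otc had no promoter peak at the threshold but had one in the pseudoreplicated list, and Cps1 had 6 distal joint peaks. Of bile acid genes, 5 of 11 were open, led by Abcb4 (14.9) and Abcb11 (10.5). In the replicates' own lists, 4 of these 11 were open in replicate 1, 2 in replicate 2 and 1 in both. Abcb11 was called in replicate 2 and not in replicate 1. None of these 4 pathways differed from other genes at the threshold (adjusted p of 0.497, 0.518, 1 and 0.797 by Fisher's exact test).

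Markers of other cell types of the fetal liver had few promoter peaks at the threshold. Promoter peaks were present at 1 of 16 macrophage genes (Mafb, signal 14; adjusted p = 0.000366, exact test), 1 of 17 granulocyte genes (Prtn3, 5.0; 0.000206) and 1 of 12 B cell genes (Ebf1, 10.6; 0.00454). They were present at 2 of 12 T and NK cell genes (Lck, 11.9, and Tcf7, 7.06; 0.0268), 2 of 16 stellate and mesenchymal genes (Pdgfra, 9.61, and Reln, 6.40; 0.00354) and 3 of 16 megakaryocyte genes (Gp1ba, 13.9, Thbs1, 6.49, and Tubb1, 5.12; 0.0163). All 6 of these shares were below that of other genes by Fisher's exact test in the joint thresholded list. The peaks of Prtn3, Thbs1 and Pdgfra were called in neither replicate's own list, and that of Tcf7 in replicate 1 and not in replicate 2. With the more permissive pseudoreplicated list only the macrophage list stayed below: the differences were -5.92 percentage points for megakaryocyte, -15.1 for granulocyte, -28.9 for B cell, -28.9 for T and NK cell and 6.58 for stellate and mesenchymal genes, none past the threshold. With the replicated list the T and NK cell list also stayed below. The megakaryocyte call was also lost with the conservative list (-27.8) and with a window of 2 kb (-23.0). Macrophage genes such as Adgre1 and Csf1r, granulocyte genes such as Mpo and Elane and the platelet genes Pf4 and Itga2b had no promoter peak at the threshold, though Mpo, Pf4 and Itga2b had one in the pseudoreplicated list. The stem and progenitor list had 8 of 20 open promoters (adjusted p = 0.354, exact test), led by Runx1 (20.3), Lyl1 (15.3), Hlf (12.8) and Meis1 (12.1), with none at Cd34 or Gata2, which had one in the pseudoreplicated list. The endothelial list had 6 of 18 (0.144), led by Gata4 (15), and the cholangiocyte list had 5 of 12 (0.615), led by Tspan8 (31.0) and Onecut2 (11.4). These 3 lists did not differ from other genes at the threshold in the joint list. In the replicates' own lists, 4 of the 12 cholangiocyte promoters were open in replicate 1 and 3 in replicate 2. The endothelial list, with 3 of 18 open in each replicate, was below other genes past the threshold in both replicates' own lists (differences of -33.4 percentage points in replicate 1 and -31.9 in replicate 2) and with the higher-signal 50% of joint peaks (-37.0). With the replicated (16.5) and pseudoreplicated (21.2) joint lists its difference was positive and not past the threshold, as was that of the stem and progenitor list (18.7 and 22.9). Of lists of other organs, 1 of 20 neuronal genes was open (Map2, 19.2; 3.76e-05), none of the muscle genes (3.76e-05) and 1 of 10 epidermal genes (Krt10, 11.4; 0.0146), and the 4 of 10 germline and pluripotency genes, led by Dazl (21.8), did not pass (0.604). In each replicate's own list, 1 of these 10 was open, and the list was below other genes past the threshold (-40.1 percentage points in replicate 1 and -38.6 in replicate 2). The epidermal call was lost with the higher-signal 50% of joint peaks (-32.5) and with a window of 2 kb (-34.2). No promoter peak was present at 37 of 39 Hox genes (adjusted p = 2.18e-09, Fisher's exact test), and neither Hoxa1 nor Hoxa5, the open pair, was called in a single replicate.

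Promoters with and without CpG enrichment differed in how often they were open. Of the 10833 genes without a CpG-rich promoter, 21.2% were open, against 84.0% of the 11105 others. When only genes without a CpG-rich promoter entered, the erythroid list (18 of 21 open against 21.1%, adjusted p = 4.08e-09) and the fetal hepatocyte list (21 of 24 against 21.1%, 8.67e-11) stayed above, and heme synthesis (3 of 3, 0.0397), coagulation (8 of 12, 0.00439) and complement (9 of 14, 0.00376) were also above by Fisher's exact test. Of the 11 lower lists, only the olfactory receptors remained past the threshold in that set. No promoter was open among the 15 macrophage, 15 muscle, 12 Hox, 9 stellate and mesenchymal, 9 epidermal and 8 neuronal genes left, the lowest share possible, so these lists could not pass as lower there. Open promoters remained at 3 of 14 megakaryocyte, 1 of 17 granulocyte, 1 of 11 B cell and 1 of 10 T and NK cell genes. Housekeeping and cell cycle genes, with 1 and 2 members left, did not pass.

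Distal peaks, those with a summit over 1 kb from every protein-coding start, were more numerous around erythroid and fetal hepatocyte genes, and also around the housekeeping control. Since this control passed too, a high count is not particular to genes of the 2 lineages. Erythroid genes had a median of 5.5 distal joint peaks within 50 kb of the gene body, against a median of 1 over 10000 random lists matched on gene length (percentile 100, permutation p = 0.0002, the smallest the permutations can give, adjusted p = 0.005). Fetal hepatocyte genes had a median of 4 against 1 (percentile 99.995, adjusted permutation p = 0.005). Housekeeping genes had 4 against 1 (percentile 99.98, adjusted permutation p = 0.00833). These 3 lists were past the threshold, no list was significantly low, and 22 did not pass by this two-sided permutation test. In the replicates' own lists, the erythroid median was 3.5 ± 0.707 (SD, n = 2) and passed in both. The fetal hepatocyte median was 3 in replicate 1 (adjusted permutation p = 0.0025) and 2 in replicate 2, where it missed the threshold (0.0567). The housekeeping median was 2 in replicate 1, where it missed the threshold (0.219), and 3 in replicate 2 (0.005). Zfpm1, which encodes the GATA1 cofactor FOG1, led the erythroid list with 17 distal peaks, and Hba-a1 had 9. Alb led the fetal hepatocyte list with 9, followed by Trf, the transferrin gene, with 7. With the higher-signal 50% of joint peaks only the erythroid list stayed past the threshold, and with each peak assigned to its nearest start the housekeeping call was lost and heme synthesis passed. Genes of 1 cluster share their distal peaks, which counted for each of them.

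The lists that did not pass included urea cycle (median 5), stem and progenitor, heme synthesis and bile acid genes (each 3), and mature hepatocyte, megakaryocyte, cell cycle and coagulation genes (each 2). Macrophage genes had a median of 1.5, granulocyte, B cell, endothelial, complement and germline genes 1, cholangiocyte and neuronal genes 0.5, and T and NK cell, stellate, muscle, epidermal, Hox and olfactory receptor genes 0. Among single members of these lists, Aurkb had 14 distal peaks, Hpd 13, Lyl1 10, Vwf, Klrb1c and Slc10a1 9 each, and Rrm2, Gp9 and Fech 8 each. Over all protein-coding genes, the median was 1 distal peak and 37.9% of genes had none. The gene model with the most distal peaks was Gm20388 (129), which spans 4435 kb and runs across other genes, followed by Fgfr2 (39), Gse1 (30), Pde4d (22), Usp7 (22), Zmiz1 (21), Sgms1 (21), BC107364 (20), Tbxas1 (20) and Btn2a2 (20).

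The globin and albumin loci show single elements, at positions chosen after their values were seen. Between Hbb-y and Olfr66 on chromosome 7, where the beta-globin locus control region lies, both replicates and the joint list had 5 distal peaks. Their joint summits stood at 103859300, 103861129, 103865933, 103870895 and 103877295, with signals of 15.8, 9.85, 15.1, 13.5 and 18.1. The olfactory receptor genes on either side of the locus were named for them: Olfr64 had 10 and Olfr66 9 distal peaks within 50 kb, and Olfr67 had a peak upstream of a start. That peak was called in the joint list and in both replicates, with its joint summit at 103793233, 1412 bp from the start. At the alpha-globin locus on chromosome 11, 3 intronic peaks of Nprl3 at 32245815, 32251026 and 32256333 had signals of 21.5, 23.4 and 25.9, above the promoter peaks of Hba-a2 (10.3) and Hba-a1 (6.71). How reads were shared between these 2 near-identical globin copies is uncertain, and so is this difference in height. Upstream of Alb on chromosome 5, summits stood at 90439348, 90447797 and 90450156, with signals of 12.1, 15.5 and 8.73 against 7.68 at the Alb promoter. A peak 2250 bp from the Afp start, at 90488487, had signal 9.02 and was called in both replicates.

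**Figure D2:**
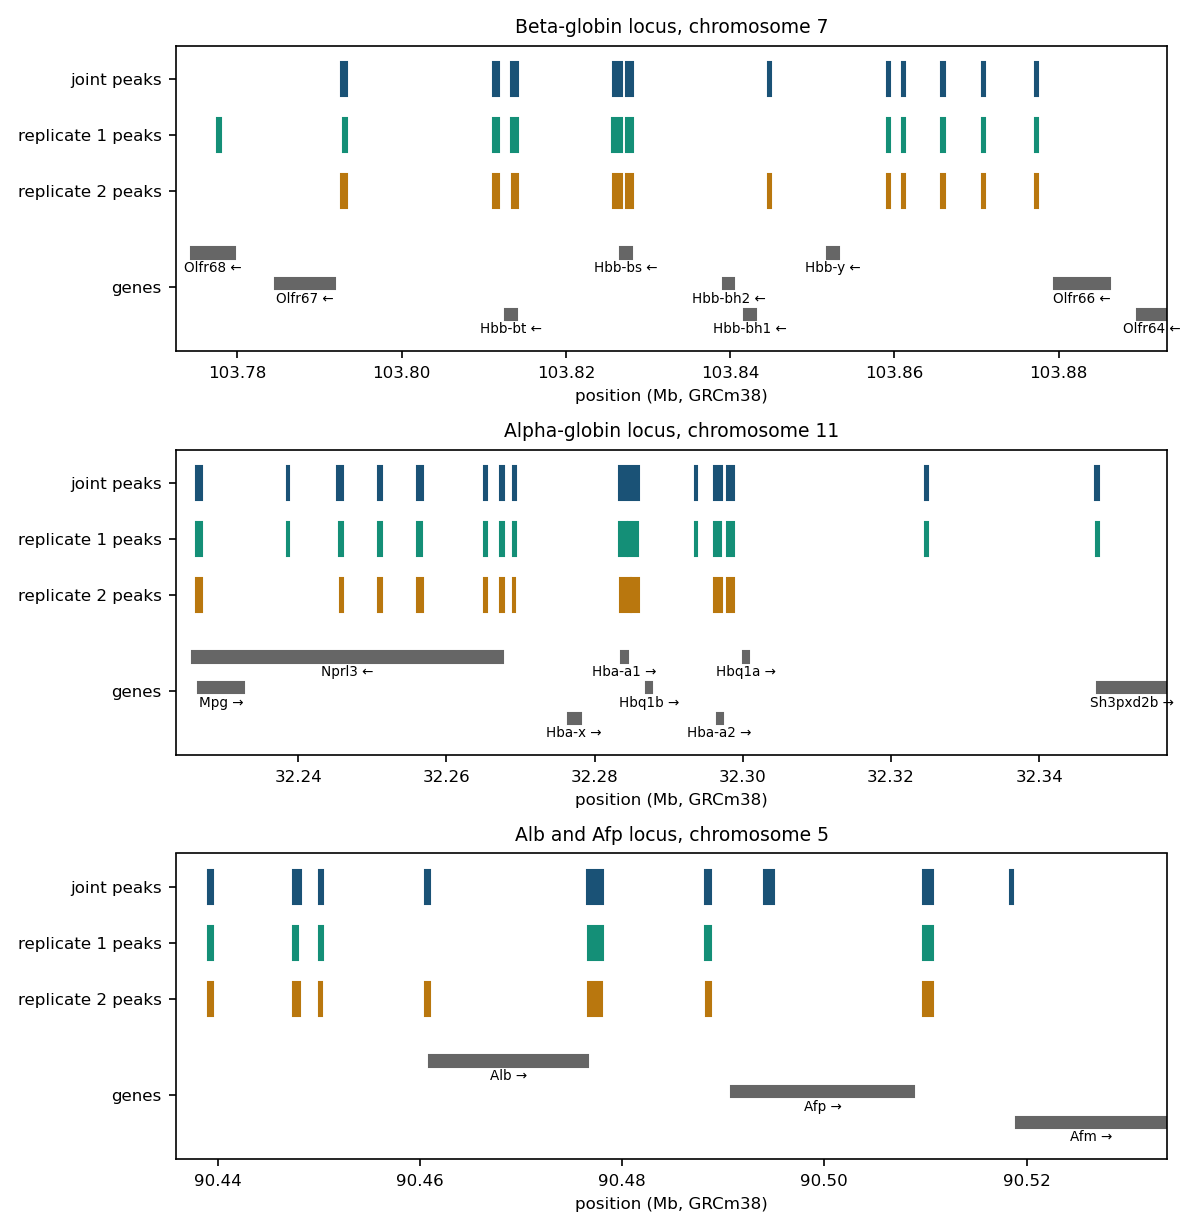
Positions (Mb, GRCm38) of thresholded peaks in the joint list and in each replicate's own list at the beta-globin, alpha-globin and Alb loci, with protein-coding genes in grey and arrows for their direction. Peaks are drawn to scale without their heights, and the 5 distal peaks between Hbb-y and Olfr66 occur in all 3 lists.

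Sites of blood and liver transcription factors were concentrated at distal summits. GATA sites (WGATAAR), bound by GATA1 in red cell precursors, occurred within 100 bp of 31.4% of the 19738 distal summits and in 11.3% of flanking windows, a ratio of 2.79 (95% interval 2.69 to 2.89). The composite of a partial TAL1 site and a GATA site was rarer and more concentrated, at 9.48% against 0.635% (ratio 14.9, 13 to 17.1). CACCC boxes of KLF1 and its relatives occurred at 19.2% against 6.32% (ratio 3.04, 2.90 to 3.20), and NF-E2 sites at 1.27% against 0.132% (9.60, 7.05 to 13.1). Of hepatocyte factors, HNF4A sites (CAAAGTYCA) had a ratio of 4.30 (3.63 to 5.08), HNF1 sites 10.4 (4.89 to 22.0), FOXA sites 2.35 (2.14 to 2.59) and C/EBP sites 2.87 (2.54 to 3.24). AP-1 sites had a ratio of 2.24 and ETS sites 3.42, but ETS sites were not above shuffled versions of their pattern in the same windows (0.881). CTCF sites, which mark insulators, had a ratio of 17.0 (12.3 to 23.5) in the joint list. In the replicates' own lists the GATA ratio was 3.11 ± 0.293, the composite ratio 18.1 ± 1.99, the HNF4A ratio 3.81 ± 0.0123, the FOXA ratio 2.34 ± 0.224 the CTCF ratio 12.1 ± 1.79 and the NRF1 ratio 25.0 ± 6.22 (SD, n = 2).

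Of the 25 patterns, 15 were enriched, 1 was depleted and 9 did not pass both thresholds (two-sided Fisher's exact test across peaks, Benjamini-Hochberg adjusted p under 0.05 and a ratio of at least 1.5 or its inverse). Besides those named, NF-Y (ratio 2.00), NRF1 (15.6), YY1 (4.61) and SP sites (5.68) were enriched. Against flanks matched on GC content, the ratio was higher for GATA (4.42) and HNF1 sites (45.0) and lower for KLF sites (1.81), which all stayed enriched. HNF1 matches were rare, at 0.228% of summits and 0.0220% of unmatched flanks. Their ratios therefore rest on few flank matches, and the GC-matched one has no interval. NRF1 (7.78) and SP sites (2.27) stayed enriched with lower ratios, and YY1 sites (2.50) did not pass. The adjusted p of the enriched patterns ranged from 0 at the precision of the software to 0.0113 for YY1. PU.1 sites of myeloid and B cells (1.42), RUNX (1.36), ONECUT (1.05), NR5A2 (0.759), TEAD (0.903), REST (0.835), octamer (0.863), p53 family (1.38) and RFX sites (4.61, adjusted p = 0.0676, exact test) did not pass both. Against GC-matched flanks, RUNX (1.73), ONECUT (2.36) and octamer sites (1.56) were enriched. PU.1 sites were enriched with the replicated (2.40) and pseudoreplicated (2.42) lists, and NR5A2 sites were depleted in the own lists of replicate 1 (0.640) and replicate 2 (0.621). In these own lists the REST ratio was 0.647 in replicate 1 and 0.495 in replicate 2. The RFX ratio was 11.1 in replicate 1, and none could be formed in replicate 2. MEF2 sites of muscle were depleted at distal summits (ratio 0.526, 0.446 to 0.620). That depletion did not hold against flanks matched on GC content (ratio 1.32). At the 11912 promoter summits the order differed: KLF sites occurred at 45.4%, SP sites at 21.5% and NF-Y sites at 15% of them, and GATA sites at 4.62%, below their flanks (ratio 0.413). Promoter summits had a median GC content of 65.7% and their flanks 44.8%, and these windows were not matched on GC.

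**Figure D3:**
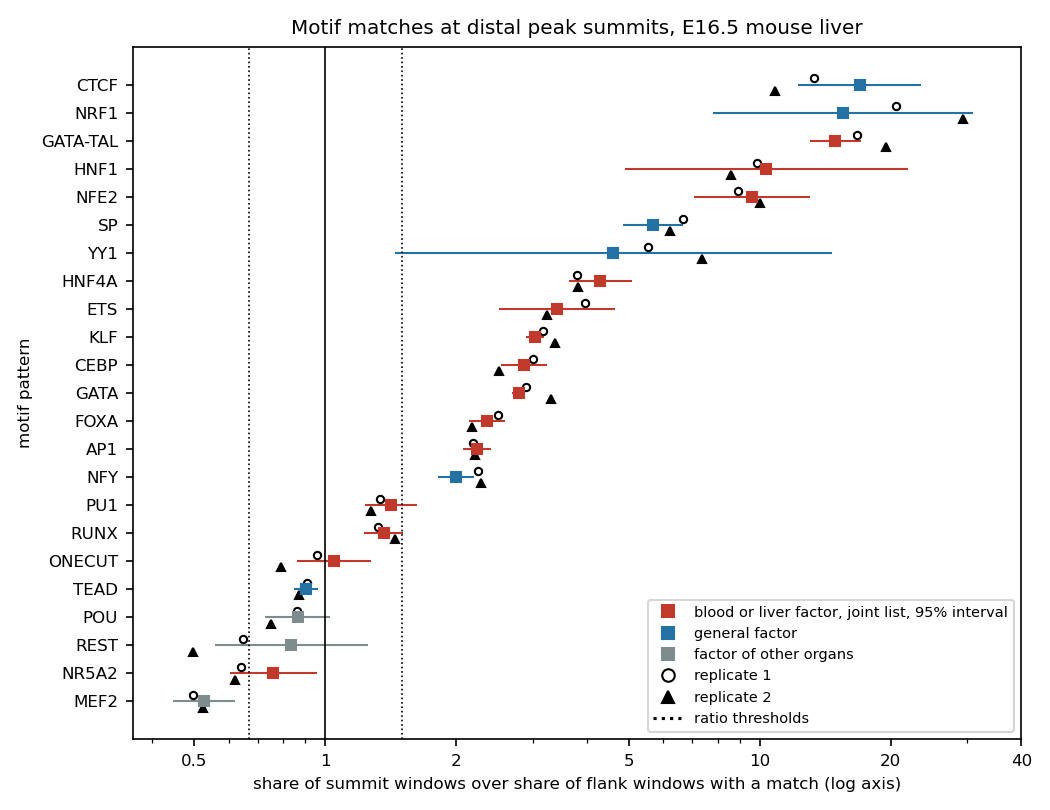
Ratio of the share of distal summit windows to the share of flank windows with a match, on a log axis, for 23 motif patterns, with 95% intervals for the joint list (squares) and ratios from replicate 1 (circles) and replicate 2 (triangles). The p53 family and RFX patterns had too few matches to draw; in the joint list CTCF stood at 17.0 and MEF2 at 0.526.

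Peaks lay at promoters far more often than their share of the genome. Of the joint peaks, 11912 (37.6%) had their summit within 1 kb of a protein-coding start, 2.48% lay in other exons, 33.3% in introns and 26.5% between genes. The promoter share was 19 times that of the genome (1.98%), and the intergenic share 0.434 times. In the replicates' own, shorter lists the promoter share was 45.2% ± 2.21 (SD, n = 2), and in the longer pseudoreplicated joint list it was 22.8%. Promoter peaks were higher and wider than distal ones: the joint medians were 15.1 and 9.20 in signal and 853 and 427 bp in width. The height of a merged peak is that of its highest summit. Several summits were present in 75.5% of promoter and 29.8% of distal joint peaks, which may add to the difference in height. The ratio of median signals was 1.44 ± 0.0248 over the replicates' own lists (SD, n = 2). The X chromosome held 4.14 joint peaks per Mb against 12.6 on the autosomes, a ratio of 0.330, and 0.344 ± 0.00432 in the replicates (SD, n = 2). It also held 0.747 peaks per protein-coding gene, below each autosome, where the lowest was 1.03 on chromosome 7. Chromosome 11 was densest at 19.5 peaks per Mb, and the Y chromosome held 8 peaks.

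The 10 highest distal peaks, by signal, were 9 intergenic peaks, meaning outside protein-coding genes, and 1 in an intron of Gnb1l. Named by the nearest protein-coding start, they lay near Pak3 (signal 60.1), Abcb11 (59.5), Rtl10 (53.7), Cdh20 (51), G6pd2 (48.9), Gm5426 (48.3), Epm2a (48.0), Hic2 (45.1), Igf2bp3 (43.3) and Gm12887 (42.6). The first lay on the X chromosome from 143482935 to 143483180 and the second on chromosome 2 from 69355469 to 69355735, 13 kb from the Abcb11 start. Several were remote: the peak named for Cdh20 was 2140 kb and that for G6pd2 1766 kb from the start. All 10 were called in both replicates.

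The replicates shared most of their peaks. Of the replicate 1 peaks, 81.1% (exact 95% interval 80.6 to 81.6%) overlapped a replicate 2 peak by at least 1 bp, and 89.8% (89.4 to 90.2%) of the replicate 2 peaks overlapped a replicate 1 peak. Peaks placed at random on the same chromosomes overlapped in 1.14% and 1.27% of cases over 100 shuffles. Replicate 1 had 4771 peaks that replicate 2 lacked, and replicate 2 had 2315 that replicate 1 lacked. Across the 95024 summits of the joint ranked list, peak height as −log10 p in the 2 inputs correlated with Spearman's rho of 0.824 and Pearson's r of 0.876 on log2 values. These are correlations across peaks, which are not independent replicates. Both cover only summits with a −log10 p of at least 2.00 in each input, so peaks found in 1 input only did not enter. With 1 summit per interval the values were 0.895 and 0.943.

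**Figure D4:**
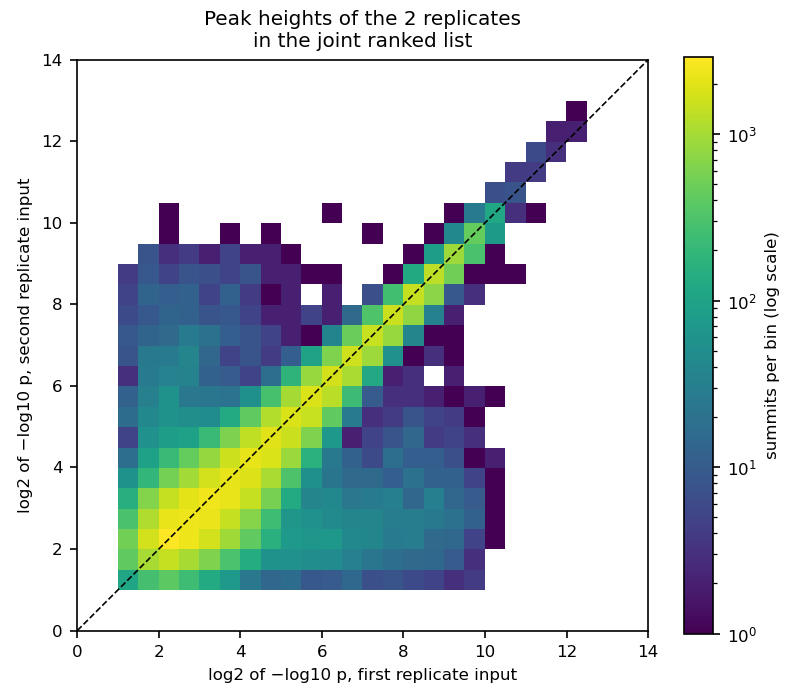
Height of each summit of the joint ranked list in the 2 replicate inputs, as log2 of −log10 p on both axes, with colour for the number of summits per bin on a log scale and a dashed line of equality. The 95024 summits follow the line with Spearman's rho of 0.824, with a scatter of summits that were high in 1 input and low in the other.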

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

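The tests in this part were set down before their results were seen. Signals in data that no comparison used led to 2 results here. The second joint ranked list held 179 intervals on unplaced or unlocalised scaffolds, which entered no comparison. It also held 987 merged intervals on main chromosomes that overlap no joint pseudoreplicated peak.

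These 987 intervals had a median −log10 p of 4.43 against 26.6 in the kept intervals, but the 10 most significant of them ranged from 2245 to 10540, and 1 of those, on chromosome 1 from 24611586 to 24616165, matched the mitochondrial genome over its whole length. As a cause of the set, mitochondrial sequence was argued against: 1.87% of the bases of these intervals matched the mitochondrial genome, where over 50% was required. Near-identical copies on the assembled main chromosomes were argued against too as a cause of most of the set. Of these intervals 6.79% had one, and 2.94% of a random sample of 987 kept intervals did, an excess of 3.85 percentage points. Of the 987 intervals, 6.18% had a −log10 p above the median of the kept ones. Copies behind these stronger intervals alone could not have reached the bound set for this test, so it does not decide their cause. Both results concern the set: of its 10 most significant intervals 3 had a second copy, and for these, the mitochondrial match among them, copies may still account. Copies missing from the assembly were not searched, so copies of that kind are left open for any of the intervals. No biological explanation was tested.

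Of peaks called in 1 replicate only, 4018 of 4771 in replicate 1 and 1880 of 2315 in replicate 2 were distal. For the distal ones, a difference in recovery of GC-rich fragments was argued against, as their median GC differed by 0.498 percentage points. Promoter peaks called in 1 replicate only did not enter this comparison, so it does not cover them. Of all single-replicate peaks, 93.5% overlapped the other replicate's ranked list, as the calling threshold requires. Ranked lists hold weak peaks too: of all thresholded peaks, 98.7% in replicate 1 and 99.5% in replicate 2 overlapped the other's. A different makeup of the pools could also leave a weaker peak there, so this overlap does not give the cause. Among the distal ones, GATA matches occurred in 21.2% of the replicate 1 set and 32.4% of the replicate 2 set (odds ratio 0.559). Matches to a hepatocyte factor (HNF4A, HNF1, FOXA or C/EBP) occurred in 13.4% and 9.63% (odds ratio 1.45). A different makeup of the 2 pools may give such values, but with 1 pool each and lists of unequal length it was not told apart from the calling threshold.

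The 10 highest distal peaks were weighed as well. That they are promoters of genes outside the protein-coding set was argued against, since 1 of the 10 lay within 1 kb of any annotated start. Pile-up from near-identical copies cannot be told apart from a property of these sites: 3 of the 10 had such a copy, between the bounds of 5 and 1 set for this test, and copies missing from the assembly were not searched. A GATA match was present in 1 of the 10 and a CTCF match in none. No biological explanation was tested.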

How the results depend on the processing

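Of 97 values of leading results under the alternatives, 51 stayed the same and 46 moved. A count was the same within 1.5 times the main count, and other values within 1 SD of the replicates or, for correlations, inside their 95% interval across peaks, which is narrow. Of 718 values of single lists and motifs, 629 stayed the same, 35 became weaker, 39 became stronger and 15 reversed. A list or motif past the threshold in neither setting counted as the same. The cause of each move was not tested, unless the setting itself gives it. Without read counts, what depth limits could not be measured here.

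Intervals as deposited, which count each summit, numbered 55222 in the joint list, 43012 in replicate 1 and 41162 in replicate 2, and gave an X to autosome ratio of 0.349. The share of replicate 1 peaks found in replicate 2 was 73.1% with pseudoreplicated peaks and 96.6% for the 50% of peaks with the highest signal. That of replicate 2 peaks was 99.3% for the higher-signal 50% and 83.5% with the same number of top peaks from both. Rho was 0.831 for thresholded peaks, 0.774 for distal peaks and 0.895 with 1 summit per interval, and r was 0.832, 0.846 and 0.943.

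The promoter share was 43.7 to 46.8% without 1 of the replicates, 23.8% with the replicated and 22.8% with the pseudoreplicated list, 53% for the higher-signal 50%, 34.3% with a window of 500 bp, 41.1% with 2 kb and 41.4% with starts of all genes. The signal ratio of promoter to distal peaks was 1.42 to 1.46 without 1 of the replicates, 2.46 with the pseudoreplicated list, 1.74 with 500 bp and 1.53 with 2 kb. The X to autosome ratio was 0.341 to 0.347 without 1 of the replicates.

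Promoter lists higher than other genes numbered 3 with the higher-signal 50% of peaks and 6 with the pseudoreplicated list (5 in the main setting). Lower promoter lists numbered 7 with the replicated list, 6 with the pseudoreplicated list and 1 among genes without a CpG-rich promoter, but 14 without replicate 1 or without replicate 2, 13 with the higher-signal 50% 12 with a window of 500 bp, 10 with the conservative list and 9 with a window of 2 kb (11 in the main setting). The difference from other genes reversed for fetal hepatocyte genes with the higher-signal 50% (-11.3 percentage points), for megakaryocyte genes without a CpG-rich promoter (0.216) and for stellate and mesenchymal genes with the pseudoreplicated list (6.58). Higher distal lists numbered 1 with the higher-signal 50% (3 in the main setting). Lower distal lists numbered 1 with the replicated list, 1 with the pseudoreplicated list, 1 with a distance of 100 kb and 1 with matching on gene length and neighbouring genes (0 in the main setting).

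Enriched motifs numbered 7 at promoter peaks (15 in the main setting). Depleted motifs (1 in the main setting) numbered 2 to 3 without 1 of the replicates, 3 with the higher-signal 50%, 2 with a window of 50 bp to each side, 0 with GC-matched flanks, 0 with shuffled patterns and 7 at promoter peaks. Median GC was 65.7% at promoter summits and 44.8% in their flanks, and GC was not matched there. Ratios that reversed at promoter peaks were those of GATA (0.413), AP-1 (0.729), RUNX (0.336), HNF4A (0.847), FOXA (0.571) and ONECUT (0.296). Those that reversed with shuffled patterns were ETS (0.881), NR5A2 (4.98), MEF2 (1.10) and POU (2.44), and with GC-matched flanks MEF2 (1.32) and POU (1.56).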

Other observations

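Gata1, the gene of the main erythroid GATA factor on the X chromosome, had a promoter peak from 7967768 to 7968155 with signal 9.95 and a stronger distal peak, with its summit at 7971469 and signal 13.9, inside the gene. Both were called in both replicates. The alpha-globin locus had a further distal peak at 32269154 with signal 13.5, just upstream of Nprl3, and one at 32324812 with signal 8.99 on the far side of the genes, called in replicate 1 and not in replicate 2. These positions were chosen after their values were seen.

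A hypothesis set down before its test was that elements near genes of each lineage carry the sites of that lineage's factors. Distal joint peaks within 50 kb of erythroid genes (162 peaks) were compared with those within 50 kb of fetal hepatocyte genes (107 peaks), without peaks near both. GATA matches occurred in 41.4% of the erythroid set and 16.8% of the hepatocyte set (odds ratio 3.49, 95% interval 1.92 to 6.32, two-sided Fisher's exact p = 1.74e-05, adjusted p = 0.000436 over the 25 patterns). HNF4A matches occurred in 0 of the 162 and in 9 of the 107 (odds ratio 0.0319 with 0.5 added to each cell, Fisher's exact p = 0.000202, adjusted p = 0.00168). The composite of TAL1 and GATA sites followed GATA (17.3% against 1.87%, adjusted exact p = 0.000481) and C/EBP followed HNF4A (0 against 8 peaks, adjusted p = 0.00333). FOXA matches did not differ (3.70% against 3.74%, adjusted exact p = 1), nor did any of the other 20 patterns pass the threshold. Both lineage tests came out as the hypothesis required, which is consistent with separate sets of elements in the 2 lineages of this mixed tissue. Peaks within a locus are not independent, so these p-values may be too small.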
